A study of Mus musculus with 18 samples.

How the data were processed

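Small RNA was sequenced from the left and right eyes, lungs and testicles of male C57BL/6 mice aged 8 to 12 weeks, per the labels. The 18 libraries fall into 6 groups of 3, left and right of each organ. Per the labels' protocols, total RNA was extracted with a spin-column kit and libraries were prepared by the BGI-500 procedure. The submitters' processing notes name the genome build GRCm38.p6. The aligner, the counting program, the treatment of multi-mapping reads and of strand, and whether molecular identifiers were used are not given in the sources used here.

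The deposited values are whole-number counts per mature miRNA, not normalized, in 1 table per library, per the file headers and the values themselves. Each table listed 1431 miRNAs, of which 488 had fewer than 10 counts summed over all libraries. Total counts were 2451484 to 2680204 in the eye, 2538402 to 2790471 in the lung and 952608 to 1893132 in the testicle. A count of 0 allows up to 3 counts, which is 1.08 to 1.22 counts per 1e6 (CPM) in an eye or lung library and 1.58 to 3.15 CPM in a testicle library. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. In 10 sets of names, 22 in all, every library had identical counts under each name of the set. The 12 surplus names held 3.64% to 5.54% of a testicle library's counts and at most 0.408% of any other library's, and they were kept.

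Counts were tested with edgeR 4.0.16 in R 4.3.3: trimmed mean of M values (TMM) scaling, the filterByExpr filter by group, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Left and right were compared within each organ on its 6 libraries, and over all 18 libraries with organ and side as additive terms. Whether the side difference varied between organs was tested jointly on 6 group means. Each pair of organs was compared in the same fit of 6 groups, as the mean of both sides of an organ against the mean of both sides of the other. The labels do not say whether left and right libraries of an organ came from the same mice. If they did, n = 6, the SEs and the p values between organs overstate the replication. Of the 1431 miRNAs, 642 passed the filter over all libraries and 789 were left out. A miRNA was called organ-enriched, or depleted, where it differed from each of the other 2 organs in the same direction with an adjusted p under 0.05 and a log2 fold change of at least 1. CPM values beside organ or side comparisons are TMM-scaled, while values set against a floor of 3 counts over an organ use the library totals. The distance between sides was the mean Euclidean distance of log2(CPM + 1) between left and right libraries minus that within a side, with an exact one-sided permutation over 10 splits.

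The text names miRNAs by a rule. For each organ it takes the 12 enriched miRNAs whose smaller log2 fold change was largest, among those with a mean of at least 50 CPM and every library of the organ above every other library. It adds 5 depleted miRNAs by the same criteria and the 5 most abundant ones. For left against right it takes the called miRNAs or, with fewer than 5, those with the 5 lowest unadjusted p values, and for the joint test the 3 lowest. For each list it takes up to 4 members with the highest mean CPM. The full statistics are printed for part of these.

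Lists of miRNAs written from general knowledge were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and adjustment over the lists of a comparison, where at least 3 members were tested. Camera compares the members of a list with all other tested miRNAs, so its direction is relative to those. The 18 lists were the sensory cluster 183/96/182, the neural list, the list for pigment epithelium, lens and cornea, the imprinted Dlk1-Dio3 cluster, the X-linked miR-506 family, the miR-34/miR-449 family, the epithelial 200 family, the leukocyte, erythroid and endothelial 126 lists, smooth muscle 143/145, striated muscle, gonadal somatic 202, let-7, miR-30, the 17-92 and paralogue clusters, the Nodal pathway list, and hypoxia and acute response. They held 265 entries, 249 of them in the tables and 217 tested. Some miRNAs stand in 2 lists, such as miR-146a-5p among leukocyte and acute response miRNAs.

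Precursor positions came from the RefSeq gene table of GRCm38.p6, which gave a position for 1425 of the 1431 miRNAs, and overlapping genes from the GENCODE M21 annotation. Each procedure was tested on simulated counts with 200 miRNAs changed by 1.5, 2, 4 or 8 times. For 4-fold changes it recovered 100% in left against right eye, 64.4% in lung and 91.7% in testicle. For 2-fold changes it recovered 63.8%, 4.17% and 38.8%. Of the simulated calls, 5.63%, 7.23% and 1.69% were false in these comparisons. In the organ comparisons it recovered 79.2% (eye against lung), 59.2% (eye against testicle) and 51.0% (lung against testicle) of 2-fold changes. These simulated organs had 1 averaged profile apart from the miRNAs changed in 1 organ. Real organs differed in most miRNAs, so the rates do not cover effects of scaling between organs.

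Before the data were examined, the design, the naming rule and the lists were fixed, apart from the pairing of replicate numbers. The decision not to pair them was made after blocked results were seen. These alternatives were also fixed beforehand: DESeq2 1.42.0, limma-voom, relative log expression scaling, library sizes alone, no filter, and at least 10 CPM in 3 libraries. The replicate number as a block, an estimated correlation for lists and each side alone or both summed were fixed too. So were a log2 fold change of at least 2 and leaving out each library in turn. Other alternatives were chosen after seeing the data: identical names merged, miRNAs with uneven counts within an organ left out, 2 sets of libraries left out, another reference library for TMM, and for lists the replicate block together with the estimated correlation. Positions, tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Targets of the miRNAs and the raw reads were not analysed here.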

Results

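MicroRNAs were counted in left and right eyes, lungs and testicles of male C57BL/6 mice, with 3 libraries in each of 6 groups. Each eye library held 838 to 925 miRNAs with at least 1 count, each lung library 696 to 852 and each testicle library 759 to 840. In the eye, miR-204-5p held the largest mean share of counts (4.99% ± 0.151, SD, n = 6), followed by miR-183-5p (4.93% ± 0.257). In the lung, miR-126a-3p held 5.47% ± 0.529 and miR-26a-5p 5.03% ± 0.455. In the testicle, miR-449a-5p held 6.81% ± 1.10 and miR-22-3p 4.41% ± 0.353. Log2 CPM correlated across miRNAs with a median r of 0.984 between eye libraries of the same side and 0.984 between opposite sides. These medians were 0.976 and 0.982 in the lung and 0.965 and 0.965 in the testicle. Between organs the median r was 0.781 for eye and lung, 0.697 for lung and testicle and 0.561 for eye and testicle. MiRNAs are not independent replicates in these correlations. The first principal component (61.1% of the variance) and the second (29.7%) separated the 3 organs, with no separation of the sides.

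The comparison of eye and lung asked which miRNAs distinguish these organs. The photoreceptor-associated cluster of miR-183, miR-182 and miR-96 was higher in the eye: miR-183-5p had 47889 ± 5639 CPM in the eye and 1653 ± 889 in the lung (SD, n = 6 each), a log2 fold change of 4.91 (SE 0.27; edgeR adjusted p 1.3e-10). The neural miR-124-3p had 41220.5 ± 12512 CPM against 50.5 ± 53.2 (log2 fold change 9.69, SE 0.80; edgeR adjusted p 1.2e-08). The lens- and cornea-associated miR-184-3p had 40368 ± 3951 CPM against 56.6 ± 57.3 (9.53, SE 0.74; edgeR adjusted p 5.7e-09). On the lung side, miR-10a-5p had 16043.5 ± 1961 CPM against 82.4 ± 34.5 in the eye (log2 fold change -7.63, SE 0.30; edgeR adjusted p 3.1e-12). The ciliated-cell miRNA miR-449a-5p had 9651 ± 3362 CPM in the lung against 124 ± 27.9 in the eye (-6.30, SE 0.26; edgeR adjusted p 4.0e-12). With edgeR, 384 of 642 miRNAs differed, 227 higher in the eye and 157 lower, of which 217 and 129 differed by at least 2-fold. The balance depended on the reference library of the scaling: with left testicle 1 as reference, 196 were higher and 262 lower, and the median log2 fold change of all tested miRNAs moved from 0.00 to -0.51.

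By camera with the preset correlation, 8 lists separated eye and lung. All 57 tested miRNAs of the imprinted Dlk1-Dio3 cluster were higher in the eye (adjusted p 3.7e-16), among them miR-127-3p (8212 ± 1877 against 1349 ± 950 CPM) and miR-434-3p (2098 ± 333 against 62.1 ± 27.7 CPM). Of the neural list, 17 of 18 members were higher in the eye, all but miR-218-5p (adjusted p 2.1e-07). All 6 members of the sensory cluster (adjusted p 3.1e-04) and all 8 of the list for pigment epithelium, lens and cornea (adjusted p 4.1e-04) were higher in the eye. All 9 members of the 200 family were lower in the eye than in the lung (adjusted p 6.4e-05), with miR-200c-3p at 1875 ± 331 against 10240.1 ± 1331 CPM, and the estimated correlation gave an adjusted p of 0.080. All 8 members of the miR-34/miR-449 family were lower in the eye (adjusted p 1.8e-04), and with the estimated correlation the adjusted p was 0.080. Of 9 leukocyte miRNAs, 8 were lower in the eye (adjusted p 9.7e-05), with miR-223-3p at 55.0 ± 10.8 against 676 ± 154 CPM. Of 34 members of the miR-506 family, 8 were lower in the eye and 26 did not differ (adjusted p 0.025), and the estimated correlation gave an adjusted p of 0.40. Their levels were low in both organs, with miR-465a-3p, among the most abundant, at 3.77 ± 2.73 against 20.4 ± 15.9 CPM. Of the 8, 3 were the 3p arms of miR-465a, miR-465b and miR-465c with identical counts. These were highest in left lung 1 and right lung 3 (96 and 149 counts against at most 41 in the other lungs). The other 4 calls (Dlk1-Dio3, neural, sensory, pigment) had an adjusted p of 0.038 with the estimated correlation and the leukocyte list 0.041, and with the replicate number as a block as well these were 0.0504 and 0.0588.

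The remaining lists did not pass between eye and lung. Smooth muscle miRNAs were lower in the eye for 3 of 3 (camera adjusted p 0.0543), with miR-143-3p at 18868 ± 2626 against 36188 ± 4803 CPM. With the replicate block their camera adjusted p was 0.0428, and 0.113 with the estimated correlation as well. Striated muscle miRNAs were higher in the eye for 5 of 7 and lower for 2 (adjusted p 0.0784), with miR-206-3p at 3324 ± 1018 against 3.18 ± 2.46 CPM. The let-7 family had 6 of 11 lower (adjusted p 0.0643), the 17-92 and paralogue clusters 4 of 12 lower (adjusted p 0.0794), and the miR-30 family 1 higher and 5 lower of 11 (adjusted p 0.19). The Nodal pathway list had 1 higher and 2 lower of 6 (adjusted p 0.181), the erythroid list 4 higher of 7 (adjusted p 0.704), and hypoxia and acute response miRNAs 4 higher and 3 lower of 7 (adjusted p 0.711). Both arms of miR-126a and both of miR-202 were lower in the eye than in the lung, and these lists were too short for camera. MiR-202 was low in both organs, with miR-202-5p at 9.99 ± 7.12 against 45.8 ± 34.5 CPM and miR-202-3p at 0.19 ± 0.21 against 0.99 ± 0.92 CPM. Left lung 1 and right lung 3 had the most miR-202-5p (231 and 300 counts). The named testicle-enriched miRNAs summed were also highest there, at 30.4 and 37.3 CPM of the library totals. The named eye-enriched miRNAs summed were highest in right lung 1 and left lung 2, at 492 and 350 CPM against at most 166 in the other lungs. MiR-124-3p and miR-184-3p were highest in the same lungs as these eye-enriched miRNAs. Whether the counts of miR-202, of the miR-506 family or of these eye miRNAs came from lung cells was not tested. With left testicle 1 as the reference library, 11 of 11 let-7 miRNAs, 10 of 12 of the 17-92 clusters and 8 of the miR-30 family were lower in the eye, and with relative log expression scaling 9, 6 and 6. Adjusted over the list alone, the counts changed for 17-92 (2 lower), let-7 (4 lower) and leukocyte miRNAs (1 higher and 8 lower).

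Eye and testicle were compared to find miRNAs that distinguish a sensory organ from a gonad. The X-linked miRNAs of the miR-506 family lay far apart between them: miR-871-5p had 11537 ± 2832 CPM in the testicle and 1.31 ± 1.19 in the eye (SD, n = 6 each), a log2 fold change of -13.09 for eye against testicle (SE 0.76; edgeR adjusted p 1.1e-10). The gonadal miR-202-5p had 44376 ± 3686 CPM in the testicle and 9.99 ± 7.12 in the eye (-12.21, SE 0.70; edgeR adjusted p 1.0e-10). In the other direction, miR-211-5p had 35997 ± 3057 CPM in the eye and 229 ± 103 in the testicle (7.32, SE 0.61; edgeR adjusted p 9.7e-09). Its relative miR-204-5p differed less, with 48430.4 ± 4480 against 15089.7 ± 4478 CPM (1.71, SE 0.45; edgeR adjusted p 0.0025). With TMM scaling the abundant miR-26a-5p did not differ between eye and testicle (41744 ± 4009 and 41991 ± 4509 CPM; edgeR adjusted p 0.94). This rested on the scaling: its share of the library totals was 4.30% ± 0.119 in the eye and lower in every testicle library than in any eye library. With edgeR, 509 of 642 miRNAs differed, 258 higher in the eye and 251 lower, of which 225 and 228 differed by at least 2-fold. With left lung 1 as the reference library, 321 were higher and 219 lower, and the median log2 fold change moved from 0.05 to 0.56.

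Between eye and testicle 7 lists passed by camera. All 34 tested members of the miR-506 family were lower in the eye (adjusted p 5.5e-13; 0.044 with the estimated correlation), and all 6 of the sensory cluster were higher (adjusted p 4.9e-04; 0.044 estimated). With the block and the estimated correlation the adjusted p of these lists was 0.099. For the other 5, the estimated correlation removed the call. Of the Dlk1-Dio3 cluster, 47 of 57 were higher in the eye and 10 did not differ (adjusted p 8.0e-08), while the estimated correlation gave an adjusted p of 0.21. Among those 10 were miR-379-5p and miR-411-5p, at 1384 ± 251 against 1397 ± 328 and 2658 ± 473 against 2088 ± 461 CPM. Of the neural list, 16 were higher and 2 lower (adjusted p 4.9e-05), with an adjusted p of 0.13 under the estimated correlation. All 8 members of the miR-34/miR-449 family were lower in the eye (adjusted p 3.0e-04; adjusted p 0.13 estimated), including miR-34a-5p at 3102 ± 308 against 51121 ± 9290 CPM. All 6 Nodal pathway miRNAs were lower (adjusted p 0.015; adjusted p 0.24 estimated), with miR-15b-5p at 295.5 ± 58.2 against 6087 ± 674 CPM. Of the list for pigment epithelium, lens and cornea, 7 were higher and miR-203-3p was lower (adjusted p 0.039; adjusted p 0.25 estimated). Adjusted over the list alone, the same counts resulted in these 7 lists. The let-7 family, which did not pass (adjusted p 0.55), had a median log2 fold change of -0.17 and a mean of 0.41, and the sign of its median, like that of miR-126a, changed with the scaling.

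Lung and testicle were compared in the same way. The 200 family was higher in the lung: miR-200c-3p had 10240.1 ± 1331 CPM in the lung and 414 ± 67.6 in the testicle (SD, n = 6 each), a log2 fold change of 4.63 (SE 0.18; edgeR adjusted p 6.0e-12). The lymphocyte-associated miR-150-5p had 9002 ± 1755 CPM against 723 ± 168 (3.64, SE 0.20; edgeR adjusted p 7.6e-11). In the testicle, miR-34b-3p had 32265 ± 9633 CPM against 2166 ± 815 in the lung (-3.89, SE 0.28; edgeR adjusted p 1.6e-09), and miR-449a-5p had 79682 ± 15023 against 9651 ± 3362 (-3.05, SE 0.22; edgeR adjusted p 2.1e-09). With edgeR, 491 of 642 miRNAs differed, 176 higher in the lung and 315 lower, of which 142 and 294 differed by at least 2-fold. This balance also followed the reference library, with 233 higher and 267 lower for left lung 1, and 225 and 274 for left testicle 1. The median log2 fold change was -0.90 at first and -0.31 and -0.37 with these references.

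Between lung and testicle 6 lists passed by camera, and none did with the estimated correlation. All 34 members of the miR-506 family were lower in the lung (adjusted p 3.8e-10; adjusted p 0.076 estimated), and all 9 of the 200 family were higher (adjusted p 1.8e-06; adjusted p 0.15 estimated). Of 9 leukocyte miRNAs, 8 were higher and miR-342-3p was lower (adjusted p 0.0016; adjusted p 0.13 estimated). Of 8 members of the miR-34/miR-449 family, 7 were lower (adjusted p 0.019; adjusted p 0.26 estimated). Of 11 let-7 miRNAs, 6 were higher (adjusted p 0.019; adjusted p 0.43 estimated), among them let-7i-5p at 27962.7 ± 5464 against 12638 ± 3422 CPM. With library sizes alone, left lung 1 or left testicle 1 as the reference, 10 of the 11 let-7 miRNAs were higher. Of the Dlk1-Dio3 cluster, 45 of 57 were lower (adjusted p 0.0499; adjusted p 0.54 estimated), against 36 with library sizes alone, 31 with left lung 1 and 33 with left testicle 1 as the reference. Adjusted over the list alone, these 6 lists had the same counts. For the erythroid list the median (-0.81) and mean (-0.68) were lower in the lung, with 0 of 7 members called. Camera placed this list above the other tested miRNAs, and the median of all tested miRNAs was -0.90. The sensory cluster, also placed above the others, had a median of 0.40 and a mean of -0.08. Neither list passed.

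Organ-enriched miRNAs were those that stood apart from both other organs, and 165 were enriched in the eye. By the smaller of its log2 fold changes, the muscle miRNA miR-206-3p stood furthest apart in the eye among the named miRNAs, with 3324 ± 1018 CPM against 3.18 ± 2.46 in the lung and 7.18 ± 4.94 in the testicle (log2 fold changes 10.03, SE 0.54, and 9.05, SE 0.52). Its precursor lies on chromosome 1 from 20679010 to 20679082 (GRCm38.p6), in an exon of the long non-coding gene Gm28653. The brain-associated miR-384-5p had 4399 ± 936 CPM in the eye, 2.62 ± 1.73 in the lung and 12.9 ± 7.21 in the testicle, from an intergenic precursor on chromosome X (105344282 to 105344369). MiR-211-5p, from an intron of Trpm1 on chromosome 7 (64205806 to 64205911), had 35997 ± 3057 CPM in the eye and 102 ± 121 and 229 ± 103 in lung and testicle. MiR-204-5p comes from an intron of the related gene Trpm3 on chromosome 19 (22750605 to 22750672). MiR-346-5p, from an intron of Grid1 on chromosome 14, had 290 ± 66.5 CPM in the eye, 0.517 ± 0.599 in the lung and 2.08 ± 1.17 in the testicle. MiR-9b-3p had 29656 ± 3171 CPM in the eye, though its loci overlap those of miR-9 on the opposite strand and the counts of the pair may not be separate. The miRNAs most depleted in the eye were miR-449a-5p, miR-10a-5p, miR-34c-5p and both arms of miR-34b. In the eye, miR-34c-5p had 35.2 ± 8.52 CPM against 553 ± 297 in the lung and 10808 ± 1533 in the testicle.

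The lung had 74 enriched miRNAs. MiR-1298-5p had 463 ± 156 CPM in the lung, 25.8 ± 1.63 in the eye and 0.466 ± 0.551 in the testicle (log2 fold change -4.16, SE 0.31, for eye against lung and 9.81, SE 0.47, for lung against testicle), from an intron of Htr2c on chromosome X (147064905 to 147065002). MiR-146a-5p had 12056 ± 4233 CPM in the lung, 973 ± 265 in the eye and 969 ± 239 in the testicle. The endothelial miR-126a-5p had 5524 ± 1089 CPM in the lung against 694 ± 200 and 668 ± 219, from a locus in Egfl7 on chromosome 2 (26591357 to 26591429). MiR-10a-5p, from an intergenic precursor on chromosome 11 (96317165 to 96317274), had 16043.5 ± 1961 CPM in the lung and 1334 ± 369 in the testicle. MiR-141-3p had 1671 ± 503 CPM in the lung, 125 ± 45.7 in the eye and 37.0 ± 8.45 in the testicle. The miRNAs most depleted in the lung were miR-184-3p, miR-129-5p, miR-204-5p, miR-9-5p and miR-135a-5p, of which miR-9-5p had 10.99 ± 4.09 CPM against 8235 ± 1006 in the eye and 401 ± 25.0 in the testicle. The number of lung-enriched miRNAs was 133 without right eye 2, where the reference library became left testicle 3, and 123 with left testicle 1 as the reference library.

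The testicle had 186 enriched miRNAs, led by the miR-506 family. MiR-743a-3p had 2671 ± 441 CPM in the testicle against 0.318 ± 0.289 in the eye and 0.951 ± 0.863 in the lung, from an intergenic precursor on chromosome X (66776757 to 66776818). MiR-547-5p, miR-7223-5p and miR-742-5p had 0 counts in all eye and lung libraries. Against a floor of 3 counts over the 6 libraries of the other organ, miR-547-5p (91.1 ± 15.3 CPM of the library totals) was at least 463-fold higher than in the eye and at least 485-fold higher than in the lung. MiR-7223-5p was at least 452-fold and 473-fold higher than in eye and lung, from chromosome 11 (107996848 to 107996916) within an intron of Prkca on the opposite strand. MiR-202-3p had 3 counts over the 6 eye libraries and was 11576.5-fold higher in the testicle (95% counting interval 3961 to 56135), from chromosome 7 (139957689 to 139957760) in an exon of the long non-coding gene Gm2044. Counts of miR-465c-5p and miR-742-5p were uneven between testicles: miR-465c-5p had 12152, 10607 and 22 in the left and 6956, 23375 and 10204 in the right ones. The 3p arms of miR-465a, miR-465b and miR-465c had identical counts, so which of these precursors gave them is uncertain. The most depleted miRNA in the testicle was miR-490-5p, with 1.05 ± 0.651 CPM against 157 ± 33.3 in the eye and 201 ± 209 in the lung, from an intron of Chrm2 on chromosome 6.

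**Figure D1:**
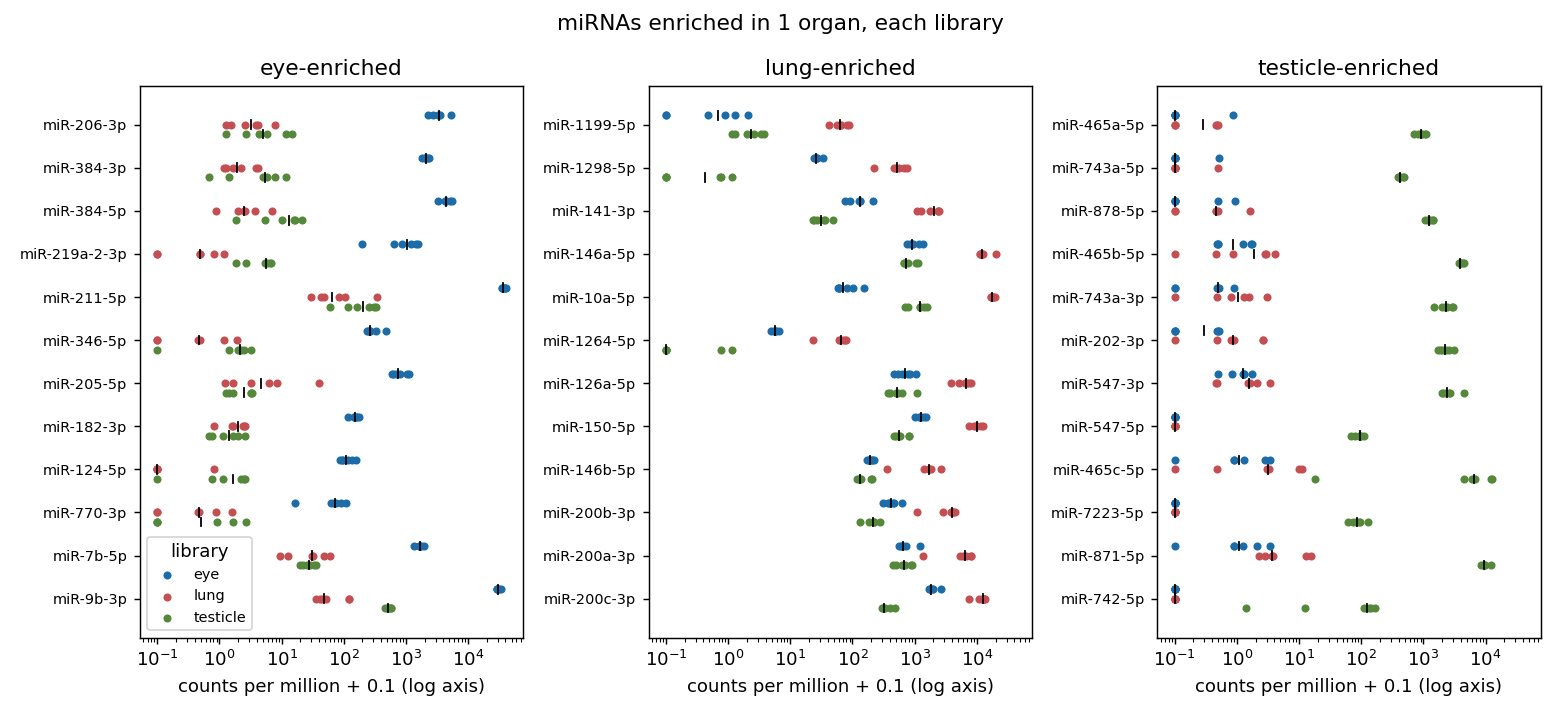
CPM of the library totals plus 0.1 on a log axis for the 12 named miRNAs enriched in each organ, with a point for each of the 18 libraries coloured by organ and a bar at the median.

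In the eye 148 of the 165 enriched miRNAs had every library of the organ above all 12 others, in the lung 59 of 74 and in the testicle 170 of 186. For miRNAs not chosen by a test, the chance share with such a separation is 0.00539%. The enriched miRNAs were chosen on the same libraries, so that share is no reference for their number. The 2 contrasts behind each count share the libraries of that organ. Independent lists of the observed sizes would share 76.1, 28.5 and 104 miRNAs. Simulated libraries with nothing differing gave 0 in each organ, which does not cover effects of scaling between organs. With the organ's libraries split between the contrasts, 160 were counted in the eye, 71 in the lung and 3 fewer than the 186 in the testicle. Depleted miRNAs numbered 67 in the eye, 116 in the lung and 73 in the testicle, against 45.8, 99.4 and 49.8 for independent lists and 61, 107 and 65 with split libraries.

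Left and right eyes were compared to find miRNAs that differ between the sides of a paired organ. MiR-744-5p had the lowest p, with 248 ± 212 CPM in left and 5.48 ± 3.23 in right eyes (SD, n = 3 each), a log2 fold change of 5.501 for left against right (SE 1.31; edgeR p 0.0030, adjusted p 0.872). Its counts were 871, 15 and 1239 in left eyes and 7, 11 and 20 in right eyes, so that left eye 2 lay with the right eyes. In the lung it varied as widely within each side (1012, 20 and 1821 left, 12, 1207 and 38 right), and its precursor lies in an intron of Map2k4 on chromosome 11 (65734733 to 65734832). The red-cell miRNA miR-486a-5p, with counts identical to miR-486b-5p, had 120 ± 24.4 CPM in left and 68.9 ± 7.66 in right eyes, higher in all 3 left libraries (log2 fold change 0.80, SE 0.22; edgeR adjusted p 0.872). MiR-187-5p (0.95, SE 0.27) and miR-3535 (1.87, SE 0.59) were also higher in all left eyes, each with an edgeR adjusted p of 0.872. With edgeR, 0 of 487 miRNAs were called and 18 had an unadjusted p under 0.05. DESeq2 called 1 (17 unadjusted), miR-744-5p at an adjusted p of 0.0239 (log2 fold change 5.52, SE 1.36), and limma-voom called 0 (17 unadjusted). Without left eye 2, edgeR called miR-744-5p at an adjusted p of 9.1e-04 (log2 fold change 6.13, SE 0.42).

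The lungs of the mouse differ in lobes between the sides. MiR-148a-5p had 3.94 ± 0.194 CPM in left and 1.59 ± 0.511 in right lungs (SD, n = 3 each), a log2 fold change of 1.28 (SE 0.46; edgeR adjusted p 0.908). MiR-25-3p had 368 ± 81.3 CPM in left and 617 ± 140 in right lungs (-0.74, SE 0.33; edgeR adjusted p 0.908). MiR-100-3p had 45.5 ± 6.95 and 84.6 ± 35.1 CPM (-0.89, SE 0.41), with miR-5114 and miR-1981-3p also lower on the left at log2 fold changes of -1.39 (SE 0.64) and -1.28 (SE 0.60), all at an edgeR adjusted p of 0.908. With edgeR, 0 of 430 miRNAs were called and 1 had an unadjusted p under 0.05, while DESeq2 called 0 (7 unadjusted) and limma-voom 0 (3 unadjusted). Without a filter edgeR called miR-297c-5p (log2 fold change -8.89, SE 1.11, adjusted p 1.3e-12), which had 174 counts in right lung 2 and 0 in the other lungs. In simulated lungs 2 of 48 differences of 2-fold were called (4.17%), so differences of that size were rarely detected.

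Left and right testicles differ in venous drainage and position. MiR-341-3p, from an intron of Rian on chromosome 12 (109611500 to 109611595), had 5.46 ± 1.12 CPM in left and 16.4 ± 3.97 in right testicles (SD, n = 3 each), lower in all left libraries (log2 fold change -1.54, SE 0.30; edgeR p 0.0018, adjusted p 0.574). MiR-183-5p had 1011 ± 152 CPM in left and 575.5 ± 158 in right testicles (0.81, SE 0.23; edgeR adjusted p 0.574). MiR-532-5p, from an intron of Clcn5 on chromosome X (7248402 to 7248497), had counts of 4, 21 and 5 in left and 22, 3299 and 2653 in right testicles (-7.26, SE 1.70; edgeR adjusted p 0.574). MiR-100-3p (-0.59, SE 0.16) and miR-1947-5p (-0.90, SE 0.26) were lower on the left, each with an edgeR adjusted p of 0.574. With edgeR, 0 of 464 miRNAs were called and 36 had an unadjusted p under 0.05. DESeq2 called 1 (35 unadjusted), miR-532-5p at an adjusted p of 1.7e-04 (log2 fold change -7.42, SE 1.46), and limma-voom 0 (36 unadjusted). Without left testicle 2, edgeR called miR-743b-3p (log2 fold change 9.90, SE 0.37, adjusted p 3.2e-04), and without right testicle 1 it called miR-532-5p (-7.89, SE 0.52, adjusted p 0.0062).

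Over all organs, miR-449c-5p was higher on the left (log2 fold change 1.74, SE 0.38; edgeR p 2.2e-04, adjusted p 0.143), though it had at most 15 counts in any library. MiR-7a-5p (-0.45, SE 0.14), let-7f-5p (-0.43, SE 0.14), let-7a-5p (-0.41, SE 0.13) and miR-363-3p (-0.73, SE 0.24) were lower on the left, each with an edgeR adjusted p of 0.762. With edgeR, 0 of 642 miRNAs were called over all organs (37 at an unadjusted p under 0.05), with DESeq2 0 (49) and with limma-voom 0 (45). Without left lung 1, edgeR called miR-449c-5p (adjusted p 0.0268), and without right lung 3 it called miR-743b-3p (adjusted p 0.0084). In the joint test of whether the side difference varied between organs, miR-743b-3p had the lowest p (edgeR p 0.0028, adjusted p 1), with counts of 4362, 5 and 4955 in left and 9, 8 and 5 in right testicles. It was called without left testicle 2 (edgeR adjusted p 0.0182). MiR-532-5p (p 0.013) and miR-466i-5p (p 0.013) followed by edgeR. With edgeR 0 of 642 were called jointly (21 unadjusted), with DESeq2 0 (22) and with limma-voom 0 (25). In simulated counts with changes in left eyes alone, the joint test called 2% of 2-fold, 57.1% of 4-fold and 58% of 8-fold changes. The changed miRNAs were drawn from all those passing the filter, among them some with almost no counts in the eye, where a change can hardly show. These shares are therefore not the power for miRNAs present in the eye. Differences could still have been missed, most clearly those of 2-fold.

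By camera with the preset correlation, erythroid miRNAs were higher in left than in right eyes (adjusted p 2.0e-04; adjusted p 0.82 estimated), with miR-451a at a log2 fold change of 0.69 (SE 0.35). Right eye 2 had the lowest CPM of the library totals among the 6 eyes for each of its 6 members. By CPM of the library totals, some miRNAs of other cells were also higher in all left than in all right eyes, such as the muscle miR-133a-3p (0.49, SE 0.26) and the leukocyte miR-142a-5p (0.77, SE 0.26). Other members of these lists had fold changes of the opposite sign, among them miR-499-5p (-0.09, SE 0.18), miR-342-3p (-0.14, SE 0.17) and miR-150-5p (-0.24, SE 0.20). The striated muscle (adjusted p 0.265) and leukocyte (adjusted p 0.60) lists did not pass by camera. Adjusted over the erythroid list alone, 2 of its 6 members were called, miR-486a-5p and miR-486b-5p with the same counts, against 0 over all miRNAs. The let-7 family was lower in left than in right lungs (adjusted p 0.0054; adjusted p 0.89 estimated) and in left than in right testicles (adjusted p 5.4e-05; adjusted p 0.89 estimated). In the testicle, let-7f-5p had a log2 fold change of -0.61 (SE 0.21) and let-7a-5p of -0.58 (SE 0.20). The 17-92 and paralogue clusters were higher in left testicles (adjusted p 0.011; adjusted p 0.89 estimated), with miR-25-3p at 0.43 (SE 0.16). No member of these lists was called over all miRNAs or, apart from the erythroid pair, adjusted over the list alone, and 1 sensory cluster member in the testicle was called over its list alone. The mean distance between sides exceeded that within a side by -0.44 in the eye (exact one-sided permutation p 0.7), -1.41 in the lung (p 0.9) and 0.06 in the testicle (p 0.5), where 0.1 is the smallest p that 10 splits can give. The between-side mean includes same-number libraries, which correlated by rank in lung and testicle. The permutation ignores this, so the distance may be understated there.

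**Figure D2:**
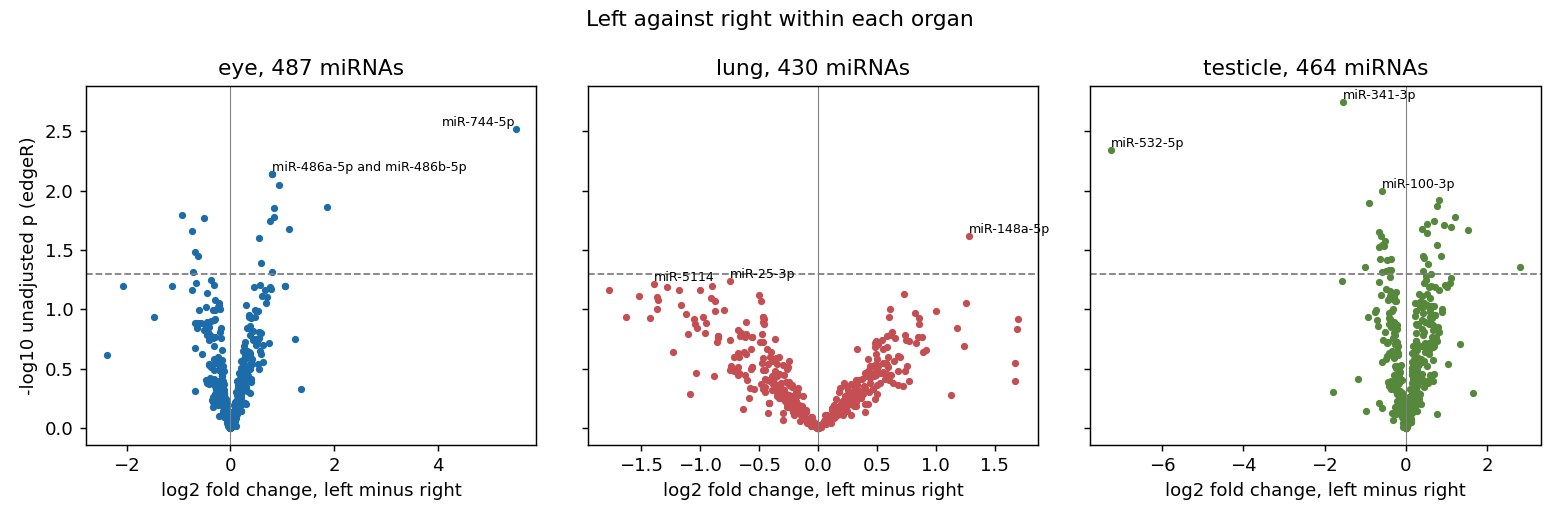
Log2 fold change of left against right and unadjusted edgeR p on a -log10 axis for each tested miRNA in eye, lung and testicle. No miRNA passed the adjusted threshold of 0.05 with edgeR, and miR-744-5p, miR-148a-5p and miR-341-3p had the lowest p in the eye, lung and testicle.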

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

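The alternatives named in processing as chosen after seeing the data are marked here as later. All other alternatives were planned. The named organ miRNAs kept their direction and their side of the threshold in all 3424 alternative values, and named left-right miRNAs in 379, with 8 moving past the threshold. The organ miRNAs were named on the same libraries for large changes and full separation, so their stability was largely set by the rule. It does not extend to all calls: without right eye 2, 351 of the 384 miRNAs called between eye and lung stayed called.

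For left against right, edgeR without a filter called 6 miRNAs in the eye, 1 in the lung and 7 in the joint test of sides between organs, and DESeq2 called 1 in the eye and 1 in the testicle. Of the later alternatives, leaving out 3 lung libraries with miR-208a called 2 in the lung (miR-297c-5p and miR-669c-5p) and leaving out both testicles numbered 1 called 1 in the testicle (miR-532-5p). Leaving out a library gave 0 to 1 in the eye, the testicle, over all organs and in the joint test. The cause was not tested.

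The 74 lung-enriched miRNAs became 29 with a log2 fold change of at least 2, a stricter limit, and 120 with sides summed. Later alternatives gave 123 with left testicle 1 as the TMM reference and 114 without the uneven miRNAs, where the reference also became right testicle 1, so the effect of leaving them out was not separated from that of the reference. Without a library the number was 72 to 133, the highest without right eye 2, where the reference became left testicle 3. There 198 miRNAs were higher and 271 lower for eye against lung, and 246 and 278 for lung against testicle.

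With the estimated correlation, the lists passing fell from 8 to 5 (eye against lung), 7 to 2 (eye against testicle), 6 to 0 (lung against testicle), and to 0 for left against right in the eye (from 1), 0 in the lung (from 1) and 0 in the testicle (from 2). With the replicate block and the estimated correlation together, a later alternative, 0 lists passed in each of these 6 comparisons, where the lowest adjusted p was 0.0504.

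The distance between sides in the testicle was -0.47 with miRNAs of at least 100 CPM. Without a library it was -1.25 to 0.54 in the eye, -3.26 to 1.38 in the lung and -0.69 to 2.14 in the testicle, with its sign reversed at 0.09 (left eye 1), 0.54 (left eye 2), 0.87 and 1.38 (right lungs 2 and 3), -0.69 (left testicle 1), -0.46, -0.55 and -0.34 (right testicles 1 to 3).

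The labels do not say whether replicate numbers mark mice, and they were not treated as pairs. Same-number sides correlated by rank at 0.32, 0.12 and 0.69 in the lung, 0.49, 0.58 and 0.38 in the testicle and -0.36, -0.15 and -0.35 in the eye, whereas Pearson values had mixed signs in each organ. By rank every lung and testicle library correlated best with its own number, a hint from the data and not from the design. The decision rests on the coefficient and was made after blocked results were seen. With the number as a block, edgeR called 383, 509 and 490 miRNAs between organs and 0 for left against right in each organ (16, 21 and 81 unadjusted in eye, lung and testicle). By camera the blocked fit added smooth muscle (eye against lung, adjusted p 0.0428), 17-92 (eye against testicle, 0.0457) and erythroid (left against right testicle, 0.0419), and with the estimated correlation the blocked values were 0.113, 0.352 and 0.890. In both testicles numbered 1, miR-451a was far below the others (222.5 and 251 CPM against at least 4503).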

Other observations

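The tests of chromosomes, of precursors without chromosome 2, of arms, of uneven miRNAs and of the organ make-up of splits were chosen only after the result was seen, as was the test of all X-linked precursors, while the test without the miR-506 family was written before its result. Counts are per mature name, and each name was assigned to every precursor that it matches, so which precursors gave the reads is unknown. Of 83 precursors of tested miRNAs on chromosome 2, 67 matched testicle-enriched miRNAs (odds ratio 12.0, two-sided Fisher exact test, Benjamini-Hochberg adjusted p 4.1e-19 over 60 tests). Of these, 60 lay in introns of Sfmbt2 (chromosome 2, 10466663 to 10518279, GRCm38.p6), matching 41 miRNAs. Of 56 precursors on chromosome 12, 39 matched eye-enriched miRNAs (odds ratio 8.14, Fisher exact adjusted p 6.1e-11). Precursors of a cluster or of the same name are not independent, so these p values overstate the evidence. For miR-324 the more abundant arm differed between organs in every library: log2 of 5p over 3p was 1.01 ± 0.47 in the testicle, -1.24 ± 0.48 in the eye and -1.43 ± 0.74 in the lung (SD, n = 6).

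The hypothesis that X-linked precursors are over-represented among those of testicle-enriched miRNAs gave an odds ratio of 1.31 (one-sided Fisher exact p 0.22; 22 of 54 against 150 of 436), which leaves it open. Without chromosome 2 the odds ratio was 2.27 (one-sided Fisher exact p 0.0063). Outside the miR-506 family, 2 of 34 X-linked precursors matched testicle-enriched miRNAs, an odds ratio of 0.119 (two-sided Fisher exact p 2.2e-04), against the hypothesis for these precursors. Without chromosome 2 as well, it was 0.208 (two-sided Fisher exact p 0.016). For lung-enriched miRNAs the odds ratio of X-linked precursors was 3.27 (two-sided Fisher exact adjusted p 0.011). For eye-enriched miRNAs it was 0.0888 (two-sided Fisher exact adjusted p 1.2e-04).

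Some miRNAs had high counts in part of an organ's libraries and far fewer, mostly almost none, in the rest, in 16 cases of 12 miRNAs. The testicle case of miR-451a differed, since its low libraries, left and right testicle 1, still held 212 and 384 counts. In the testicle, miR-871-3p had 41, 16109 and 32 counts in left and 26285, 23977 and 34 in right libraries, while miR-881-3p had 5051, 37 and 5822 and 14, 45 and 9808. Depth differed by at most 1.99 times within an organ. The gaps of at least 15-fold were taken on CPM, which already divides out depth, so comparing them with depth is no test of it. The opposite arm of the hairpin varied far less in most of the 11 cases with a usable one, with a median ratio of log2 ranges of 0.0917. The exceptions were the arms of miR-532, with ranges of similar size in the eye (ratios 0.99 and 1.01) and testicle (0.75), which did not rise and fall together. In left eyes 1 and 3 and right eye 2, miR-532-5p had 7155, 6195 and 5257 counts and miR-532-3p had 0, while in left eye 2 and right eye 3 they had 16 and 23 against 107 and 82. In right eye 1 both were present, at 5554 and 454. In the testicle miR-532-5p had 4, 21 and 5 counts in left and 22, 3299 and 2653 in right libraries, against 144, 120 and 69 and 2, 3 and 59 for miR-532-3p. A partner that made up the loss was found in 1 of 16 cases, miR-741-5p. The amount of precursor alone therefore did not account for these values in the 11 cases with a usable opposite arm. The search for a partner took 1 listed miRNA at a time and passed over those abundant in every library. It could not find a shift to an abundant name, to several names or to an unlisted sequence, so such shifts remain open. Library preparation and counting were not tested without reads, and no biological explanation was tested. Among these miRNAs were miR-744-5p, miR-532-5p and miR-743b-3p, which had the lowest or second-lowest p for left against right in the eye or testicle or the lowest in the joint test.

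In the testicle, miR-451a had 222.5 and 251 CPM in left and right testicle 1 and at least 4503 in the others, and miR-144-3p had 3.15 and 3.27 against at least 26.4. In the lung, miR-208a-3p had 2, 55 and 109 counts in left and 0, 1 and 45 in right libraries. Left lungs 2 and 3 and right lung 3 were also highest for miR-1a-3p (at least 442 against at most 103 CPM) and miR-133a-3p (at least 40.2 against at most 12.6 CPM). MiR-499-5p, miR-206-3p, miR-208b-3p and miR-133b-3p did not split the lungs in this way.

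The libraries were also split in other ways into groups of the same sizes. The 10 splits of an organ's 6 libraries are too few for a share under 0.05. For calls of left against right the real value was 0, which every split reaches whatever the data, so these counts decide nothing: 10 of 10 splits in the eye (highest other 1), 10 in the lung (highest other 1) and 10 in the testicle (highest other 2). In the lung all 9 other splits had more miRNAs at an unadjusted edgeR p under 0.05 than the real 1, up to 68, which points to differences between these libraries other than side. In the eye 1 split had 81 against the real 18 and the others 6 to 23. In the testicle 6 of the 9 other splits lay below the real 36, and the highest had 73. For lists it was 9 splits in the eye (real 1, highest other 3), 9 in the lung (real 1, highest other 3) and 4 in the testicle (real 2, highest other 3). Whether the numbers pair the sides is not established. The 3 other splits that part all same-number libraries gave 3, 0 and 3 lists in the eye, 3, 2 and 3 in the lung and 0, 1 and 0 in the testicle. They had 23, 23 and 81 miRNAs at an unadjusted p under 0.05 in the eye, 2, 10 and 15 in the lung and 10, 6 and 1 in the testicle. These splits are too few for a share under 0.05 as well. Over all organs (100 of 100 splits, highest other 8) and in the joint test (100 of 100, highest other 16) the real value was also 0, so the splits decide nothing there. Between organs, 1 of 100 splits, the real one, reached the number of calls: 384 for eye against lung (highest other 288), 509 for eye against testicle (366) and 491 for lung against testicle (339). The other splits with 5 of 6 libraries of an organ together gave 229 to 288, 278 to 366 and 283 to 339 calls in these comparisons, and those with 3 or 4 together gave at most 1, 0 and 3. Lists passing were as many in 49 of 100 splits for eye against lung (real 8, highest other 11), 46 for eye against testicle (real 7, highest other 10) and 26 for lung against testicle (real 6, highest other 9), so over all splits chance was not excluded for the number of lists. The other splits that reached it had 4 or 5 of 6 libraries of an organ together and so still held part of the organ difference. Splits with 3 together, 44, 38 and 39 of them, gave at most 5, 5 and 4 lists, and 0 reached the real number. They had at most 0, 0 and 1 miRNA calls, so camera at the preset correlation can pass lists without an organ difference. Sorting the splits by make-up was chosen after the result was seen. For enriched miRNAs 1 of 100 splits, the real one, reached 165 in the eye (highest other 1), 74 in the lung (highest other 0) and 186 in the testicle (highest other 0).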
